A study of Mus musculus with 14 samples.

How the data were processed

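RNA from mouse small intestine was measured on single-colour oligonucleotide arrays labelled with phycoerythrin. Per the labels' protocols, total RNA was extracted on columns with DNase treatment, adult crypts and villi came from 12 week old C57BL/6 mice, and E12 layers were dissected from collagenase-digested intestine and pooled. The deposited values are log2 signals, and per the submitters' processing notes the authors made them with RMA, which corrects background, normalizes across arrays and summarises the probes of each probe set. The RMA version, the software and the genome build are not given in the sources used here. The 2 value tables come from 2 array platforms with the same probe sets, but have different array medians and lower quantiles. Every test was therefore made within 1 table, apart from an alternative that used all E12 arrays. Arrays give no read depth, and the number of arrays limits the precision. A signal near the bottom of the range is mostly background, and RMA compresses differences there.

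Probe sets were named through the gene table of the platforms, which was the same for both. Of 22690 probe sets, 20393 had 1 gene symbol, 691 had several, 1555 had none and 64 were controls, and only those with 1 symbol were used, giving 12394 genes. Entrez identifiers of 20364 of these probe sets were found in the RefSeq gene table of assembly GRCm38.p6, used for names only, and 0 symbols needed an update. A gene with several probe sets was represented by the probe set with the highest mean over the arrays of the fit, and no named gene had another probe set with an opposite difference of 0.5 or more. Genes above the 30th percentile of the table's values in at least 3 arrays were tested. Sis, Olfm4 and Muc2 were to be reported but are not analysed here.

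Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with Benjamini-Hochberg adjustment over all genes of a comparison, and a gene was called at an adjusted p under 0.05. Villi were tested against crypts on the 6 adult arrays, and E12 endoderm against E12 mesenchyme on the 6 E12 arrays of the second table. Crypts and villi were each tested against E12 endoderm in 1 fit of the 4 groups in the first table, where each E12 layer has 1 array. The labels describe each adult sample as coming from a mouse and each E12 sample as a pool. They do not say whether a crypt and a villus sample that share a number came from the same animal. The p-values therefore measure only the spread between these samples. No array was a copy of another in its table, and at most 377 of 12394 gene values were the same in a pair of arrays.

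In addition, 34 gene lists were fixed before the data were examined, and each comparison was given those that fit it. Lists with at least 5 tested genes were tested with camera from limma at a preset inter-gene correlation of 0.01, again with the correlation estimated from the data, and by rank. The estimated correlation comes from fits with 4 residual degrees of freedom, which leaves that setting little power. Of the 33 lists tested per comparison, 2 passed it between the E12 layers and 0 in the other comparisons. Failing it therefore does not show that a list did not move. E12 layer lists held the genes at least 4-fold higher in a layer with an adjusted p under 0.05. Named genes followed a rule fixed before the data were examined: the 8 largest rises and the 8 largest falls with an adjusted p under 0.05 and no overlap between the groups, the 2 largest changes among the called members of each list chosen for the comparison (or the largest difference where none was called), and a fixed set of marker genes.

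The E12 samples carry replicate numbers shared by both layers. Deviations from the group mean correlated across genes at 0.21, 0.23 and 0.11 for the same-numbered samples 2, 3 and 4. These values pass the criterion of 0.1 set before the fits were compared. Endoderm replicate 3 and mesenchyme replicate 4 also passed it, at 0.13, so the check does not single out the same-numbered samples. The pairing therefore rests on the titles, and the block is given with the alternatives.

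The limma test was run on data simulated from the real means, the spreads that limma estimates and 200 changed genes, 100 at each fold size. The simulation began after the choice of probe sets and the dim gene filter, and drew each gene independently. It changed far fewer genes than were called in the data, so its rates may not carry over. In the fits with a lone E12 array, that array was given the same spread as the others. For villus against crypt (9962 genes) the test recovered 71.0% of 2-fold and 99.0% of 4-fold changes, and 5.6% of its calls were false. For the E12 layers (9442 genes) it recovered 98.0% and 100%, with 4.3% false calls. For crypt against E12 endoderm (10082 genes) it recovered 18.0% and 96.0%, with 7.3% false calls, and for villus against E12 endoderm (10082 genes) 25.0% and 94.0%, with 7.0% false calls.

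The alternatives were a trended and robust prior, no dim gene filter, a filter at the 50th percentile, the median over a gene's probe sets, leaving out probe set types prone to cross-hybridization, setting arrays to a common median, quantile normalization, leaving out each replicate in turn, blocking on the replicate number, sharing the spread of all groups in the table, and using all E12 arrays with the table as a block. Gene lists were also run under the gene-level settings, an alternative chosen after seeing the data.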

Results

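The arrays measured RNA from mouse small intestine in 4 groups, and the stated subject of the series is gene regulation between crypt and villus. Crypts are the pockets of the intestinal epithelium that hold stem, dividing and Paneth cells, and villi are the projections covered mainly by absorptive enterocytes. Each adult group had 3 arrays, from C57BL/6 mice aged 12 weeks. The embryonic groups were endoderm, the inner layer that forms the epithelium, and mesenchyme, the outer layer that forms connective tissue and muscle, taken at embryonic day 12 (E12) after collagenase digestion. Each embryonic group had 4 arrays, 3 from pools of 10 to 12 fetuses and the fourth from a pool of 35 fetuses. The values came as 2 tables, each from its own array platform, with the same 22690 probe sets. The first held the 6 adult arrays and the E12 pair from 35 fetuses, where the 30th percentile of an array's log2 signals was 5.71 to 5.88, and the second held the other 6 E12 arrays, where it was 4.70 to 4.78. Crypt replicates carry the numbers 12, 21 and 41, and villus replicates the numbers 12 and 41 and the name V275. Values are log2 means ± SD over the arrays of a group, and differences are log2 differences ± SE. Where the lower group of a gene lies under the 30th percentile of its arrays, its signal is near background. The size of such a difference and its place among the largest are not exact. Among genes named by the rule, outside the 8 largest changes, this holds for Slc15a1, Slc2a2 and Cyp3a25 in crypts and for Smoc2 and Psat1 in villi. Of the genes named after the data were seen, it holds at least for Cd3g, Dusp1, Ubd and Ifit1 in crypts. Between the E12 layers it holds for Afp, Ihh, Shh and Fgfr4 in mesenchyme. In endoderm it holds for Csf1r, C1qa, Lum, Emcn, Fabp7, Tubb3, Bmp4, Id4, Notch4 and Hoxc8. For crypts against E12 endoderm it holds for Fabp6, Vdr and Lct in endoderm and Prdm1 in crypts.

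Villi were compared with crypts to find which genes differ between the proliferating and the absorptive compartment of the adult epithelium. Genes of nutrient digestion and uptake were among the largest rises in villi. Lct, which encodes the milk sugar enzyme lactase, stood at 11.71 ± 1.0 in villi and 5.30 ± 0.26 in crypts (n = 3 each), where it lay near background. The lipid-carrying apolipoprotein genes Apoc3 and Apoa4 were 82.1-fold and 52.4-fold higher in villi. In crypts, the genes with the largest excess included the Paneth cell genes Mptx1 (26.8-fold), Pla2g2a (25.5-fold) and Mmp7 (18.8-fold), and the proliferation marker Mki67 was 12.0-fold higher there than in villi.

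The 8 largest rises in villi whose arrays did not overlap those of the crypts were Ada, Lct, Apoc3, Pmp22, Cyp3a11, 2010106E10Rik, Apoa4 and Fabp1. Ada, the purine enzyme adenosine deaminase, led them with 12.64 ± 0.91 in villi and 5.93 ± 0.11 in crypts and a limma adjusted p of 8.7e-05. Pmp22, best known as a myelin protein gene, rose by 6.34, and Cyp3a11, a drug-metabolizing cytochrome P450 gene, rose by 6.09. The uncharacterized 2010106E10Rik rose by 5.98, and Fabp1, the liver type fatty acid binding protein gene, by 5.68. The 8 largest falls were Clps, Tmed6, Mptx1, Pla2g2a, Bex1, Car8, Tent5c and Mmp7. Clps, which encodes colipase, the cofactor of pancreatic lipase, stood at 13.22 ± 0.20 in crypts and 8.08 ± 0.88 in villi, a log2 difference of -5.15 ± 0.40 with a limma adjusted p of 0.00024. Tmed6 was lower in villi by a log2 difference of -5.11, Bex1 by -4.54, Car8 by -4.41 and Tent5c by -4.38. Lct, Cyp3a11, 2010106E10Rik and Fabp1 lay under the 30th percentile in crypts, and Tmed6, Bex1, Car8 and Tent5c in villi. The adjusted p of these 16 genes ranged from 3.6e-06 to 0.00035 in the limma fit.

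Genes of cell division and of ribosome assembly fell in villi. Of 27 cell cycle genes tested, 24 were lower in villi (26 adjusted over the list alone), with a median log2 difference of -1.29. Mki67 stood at 6.52 ± 0.77 in villi and 10.11 ± 0.12 in crypts, and Top2a, a DNA topoisomerase gene used at mitosis, had a log2 difference of -2.49 (-1.25 with the median of its probe sets). The list fell as a set (camera adjusted p = 4.5e-13), and its adjusted p = 0.26 with an estimated correlation. Of 20 ribosome biogenesis genes, 16 were lower in villi (16 adjusted over the list alone), among them the nucleolar genes Ncl (-2.58, or -1.63 with the median of its probe sets) and Gnl3 (-2.42). That list had a camera adjusted p = 2.6e-10 and an adjusted p = 0.26 with an estimated correlation.

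Stem cell and Paneth cell genes were also lower in villi. Of 16 stem cell and Wnt target genes, 10 fell and 1 rose (11 and 1 adjusted over the list alone). Lgr5, the marker of crypt base stem cells, stood at 8.81 ± 0.62 in crypts and 6.64 ± 0.28 in villi, a 4.50-fold difference with a limma adjusted p of 0.002. The chloride cotransporter gene Slc12a2 (-3.34) and the matricellular gene Smoc2 (-3.31) had the largest falls of the list, while Sp5, a Wnt-responsive transcription factor gene, was the member that rose (0.94). The set gave a camera adjusted p = 3.2e-05 and an adjusted p = 0.28 with an estimated correlation. Of 7 Paneth cell genes, 6 fell (6 adjusted over the list alone), by a median of -3.96, with a camera adjusted p = 1.8e-05 and an adjusted p = 0.5 with an estimated correlation. The lysozyme gene Lyz1, made by Paneth cells, had a log2 difference of -2.60 ± 0.62 and a limma adjusted p of 0.016. Its villus arrays ran from 10.1 to 13.0, and without crypt replicate 12, 21 or 41 its adjusted p was 0.062, 0.063 or 0.051 (0.0012 to 0.077 over the alternatives). Lyz1 was the highest value of every crypt array, so its difference is not measured in full, and its probe set that is not prone to cross-hybridization gave -1.37.

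Digestive enzymes, transporters and lipid handling genes rose together in villi. Of 17 brush border genes, which encode the enzymes and structural proteins of the absorptive surface, 16 rose (16 adjusted over the list alone), by a median of 2.95. They included Lct, the sugar enzyme gene Treh (4.70) and the microvillus protein gene Vil1, which was 3.77-fold higher in villi (limma adjusted p = 0.0017). Of 19 nutrient transporter genes, 15 rose (16 adjusted over the list alone), led by the peptide carrier Slc15a1 (5.30) and the glucose carrier Slc2a2 (4.90). Of 21 fat absorption and chylomicron genes, 19 rose (19 adjusted over the list alone), and of 25 xenobiotic metabolism genes 23 rose (23 adjusted over the list alone), including Cyp3a11 and Cyp3a25 (5.26). The camera adjusted p was 2.1e-11 for the brush border, 1e-08 for transporters, 1.9e-12 for fat absorption and 8.7e-14 for xenobiotic metabolism. For each of these 4 lists the adjusted p = 0.26 with an estimated correlation.

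Mitochondrial and sterol lists differed less. Of 18 fatty acid oxidation genes, 10 rose and 2 fell (11 and 2 adjusted over the list alone), with Ehhadh (1.79) and Slc25a20 (1.36) the largest. Their camera adjusted p = 0.02 became an adjusted p = 0.82 with an estimated correlation, 0.19 after quantile normalization, and 0.066 or 0.11 without crypt replicate 12 or villus replicate 12 (0.0032 to 0.82 over the alternatives). Of 26 oxidative phosphorylation genes, 2 passed the test (0 adjusted over the list alone), Uqcrfs1 (0.87) and Ndufa1 (0.83). Quantile normalization left these at 0.35 and 0.23 with limma adjusted p of 0.18 and 0.38. Without crypt replicate 12 or 21 their adjusted p was 0.057 and 0.065 for Uqcrfs1 and 0.074 and 0.071 for Ndufa1, without villus replicate V275 it was 0.051 and 0.053, and without villus replicate 12 it was 0.056 for Ndufa1. Over the alternatives it ran from 0.0089 to 0.19 for Uqcrfs1 and from 0.0083 to 0.38 for Ndufa1. The oxidative phosphorylation set had a camera adjusted p = 0.057, with 0.00018 without crypt replicate 41 and 0.0025 without villus replicate 41 (0.00018 to 0.86 over the alternatives). Of 17 cholesterol synthesis genes, Sc5d (1.41, or 0.75 with the median of its probe sets) and Tm7sf2 (0.79) rose (2 adjusted over the list alone), and Tm7sf2 had an adjusted p of 0.063 without crypt replicate 12 and 0.084 without crypt replicate 21 (0.015 to 0.085 over the alternatives). The sterol set had a camera adjusted p = 0.2, with 0.012 without crypt replicate 41 and 0.039 without villus replicate V275 (0.0054 to 0.86 over the alternatives). Among 19 amino acid and urea cycle enzyme genes, 8 fell and 4 rose (8 and 4 adjusted over the list alone), from Psat1 of serine synthesis (-3.55) to the arginase gene Arg2 (3.10), and the camera adjusted p = 0.17.

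Goblet and enteroendocrine genes did not pass the test as sets. Of 13 goblet cell genes, 7 rose and 5 fell (7 and 6 adjusted over the list alone). Klf4, a transcription factor gene of differentiated epithelium, rose by 2.80 and the membrane mucin gene Muc3 by 2.59, whereas Atoh1 and Spdef, transcription factor genes of the secretory lineage, had log2 differences of -1.17 and -1.39. Of 18 enteroendocrine genes, 5 rose and 2 fell (5 and 2 adjusted over the list alone). The neurotensin gene Nts rose by 2.56, and Gcg, the proglucagon gene, had a log2 difference of -2.92. Chga, a general marker of hormone cells, differed by 0.25 ± 0.19 with a limma adjusted p of 0.35. Its difference was -0.10 after quantile normalization, 0.07 with the replicate block, 0.38 without crypt replicate 12 and 0.12 without villus replicate V275. As sets they had a camera adjusted p of 0.58 for goblet and 0.46 for enteroendocrine genes.

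T cell and antigen presentation genes were higher in villi. Of 16 T cell and intraepithelial lymphocyte genes, 13 rose in villi (13 adjusted over the list alone), by a median of 1.58. They were led by the granzyme gene Gzma (11.22 ± 0.67 in villi, 6.87 ± 0.18 in crypts) and the chemokine gene Ccl5 (3.58). Of 17 antigen presentation genes, 11 rose (11 adjusted over the list alone), including the class II genes H2-Aa (2.07) and H2-Ab1 (2.06), and H2-Aa had an adjusted p of 0.06 without villus replicate V275 (0.0079 to 0.06 over the alternatives). The camera adjusted p was 3.3e-07 for T cell genes and 8.5e-05 for antigen presentation, and with an estimated correlation the adjusted p was 0.51 and 0.53. Of 8 B and plasma cell genes, 3 fell (3 adjusted over the list alone): the signalling adaptor gene Blnk (-1.04), the B cell surface gene Ms4a1 (-0.59) and Xbp1 (-0.79), which secretory epithelium also uses. Xbp1 was at -0.45 with the median of its probe sets and -1.35 after quantile normalization. Their camera adjusted p = 0.099 became 0.0068 without crypt replicate 12 (0.0068 to 0.53 over the alternatives). Of 12 myeloid genes, Ptprc (1.78), a gene of all leukocytes, and Tyrobp (0.70) rose and Lyz2 (-3.44) and Csf1r (-0.57) fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.58). Lyz2 stood at 12.07 in crypts and 8.64 in villi, and whether its signal came from myeloid cells was not tested. Sp5, Atoh1, Spdef, Ms4a1, Tyrobp and Csf1r were named after their values were seen.

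Markers of the tissue under the epithelium were near equal in both groups. Of 17 stroma genes, Thy1 (0.71) and Vim (0.65) rose (0 adjusted over the list alone), with limma adjusted p of 0.038 and 0.045. Without crypt replicate 12, 21 or 41 or villus replicate V275 these became 0.086, 0.098, 0.11 and 0.082 for Thy1 and 0.057, 0.16, 0.1 and 0.13 for Vim, and Vim had 0.098 without villus replicate 41 and 0.05 with no dim gene filter. Over the alternatives the adjusted p ran from 0.024 to 0.22 for Thy1 and from 0.014 to 0.4 for Vim. In limma, 0 of 11 smooth muscle genes, 0 of 10 endothelial genes and 0 of 11 Hedgehog receptor and target genes passed the test, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 2, 2 and 3. Their largest differences were 0.41 for the muscle actin gene Acta2 (0.15 with the median of its probe sets), -0.42 for the vessel gene Esam and -0.56 for the transcription factor gene Barx1. Esam had an adjusted p of 0.029 without crypt replicate 41 and Barx1 of 0.049 without villus replicate 41, and Barx1 had 0.035 with a trended and robust prior and 0.047 with the median of probe sets. The adjusted p ran from 0.029 to 0.36 for Esam and from 0.035 to 0.22 for Barx1 over the alternatives. As sets, the 4 lists had camera adjusted p of 0.66 for stroma, 0.78 for smooth muscle, 0.58 for endothelium and 0.7 for Hedgehog genes.

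Regulators and junction genes moved in both directions. Of 27 intestinal transcription factor genes, 8 rose and 6 fell in villi (8 and 6 adjusted over the list alone; camera adjusted p = 0.54), with Creb3l3, a regulator of lipid metabolism genes, highest at 3.12. Hnf4a, a transcription factor gene of the enterocyte, stood at 12.03 ± 0.23 in villi and 11.12 ± 0.14 in crypts (limma adjusted p = 0.0056), but its difference of 0.91 became 0.30 with an adjusted p of 0.15 after quantile normalization. The adjusted p of Hnf4a was 0.075 with the median of its probe sets and 0.097 without cross-hybridizing probe set types (0.0039 to 0.15 over the alternatives). Cdx2, the intestinal identity gene, differed by 0.40 ± 0.32 (limma adjusted p = 0.39), or by 0.76 without villus replicate 41 (adjusted p = 0.031) and by -0.09 after quantile normalization (0.031 to 0.87 over the alternatives). The Cdx2 difference was 0.21 without crypt replicate 41, 0.20 without villus replicate 12, 0.23 without V275 and 0.26 with the median of its probe sets. Of 20 BMP pathway genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.2), the ligand gene Bmp2 by 2.31 and the receptor antagonist gene Bambi by -3.42. Of 20 Notch pathway genes, 5 fell (5 adjusted over the list alone; camera adjusted p = 0.19), led by the receptor gene Notch1 (-1.68, or -0.76 with the median of its probe sets) and Hes6 (-1.13). Of 25 junction and keratin genes, 10 rose and 3 fell (12 and 5 adjusted over the list alone; camera adjusted p = 0.16), with Cldn4 (2.57) and F11r (2.12, or 1.22 with the median of its probe sets) the largest. The junction set fell just under the threshold without crypt replicate 41 (0.05 after rounding; 0.025 to 0.86 over the alternatives).

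**Figure D1:**
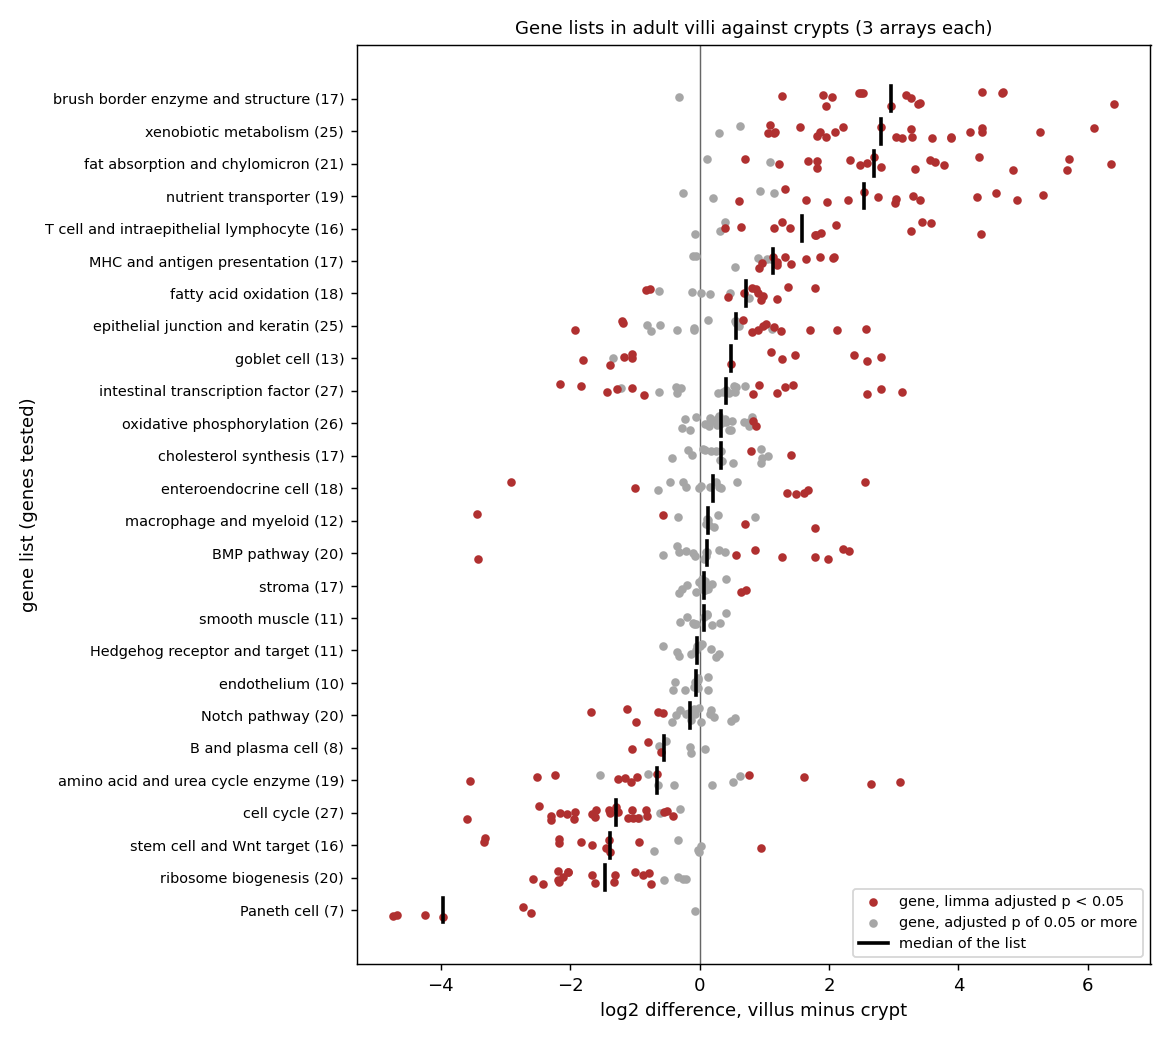
Log2 difference (villus minus crypt, horizontal axis) of every tested gene in each list fixed for this comparison (vertical axis), with a black bar at the median of each list; red points passed the limma test and grey points did not. The medians run from -3.96 for Paneth cell genes to 2.95 for brush border genes.

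Over all 9962 genes tested, 3183 changed between villi and crypts in limma, 1687 higher and 1496 lower in villi, and 4210 had an unadjusted p under 0.05. By at least 2-fold, 1033 were higher and 698 lower, a split that became 861 and 878 after quantile normalization. For 47.8% of the genes the villus and crypt arrays did not overlap, where chance gives 10% for 3 against 3. None of the 11 list calls held with an estimated correlation, as listed above. In that setting 0 of all 33 lists passed, with 4 residual degrees of freedom. It therefore cannot separate lists that moved from lists that did not. The gap between the 3′ and 5′ probe sets of the beta-actin control, a measure of RNA length, was 1.13 ± 0.159 in crypts and 0.304 ± 0.146 in villi, and it moved with all of these gene groups (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 arrays allow). The same gap for Gapdh did not (0.932 ± 0.339 and 0.978 ± 0.401, exact permutation test, two-sided p = 1). The count of changed genes was 1974 without crypt replicate 21, and 1260 with the replicate number as a block, 836 higher and 424 lower in villi.

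E12 endoderm was compared with E12 mesenchyme to find the genes that separate the layers that go on to form epithelium and its support. Epithelial adhesion genes and gut regulators were higher in endoderm, and matrix, muscle, vessel and neural genes were higher in mesenchyme. Foxa1, a pioneer transcription factor gene of endoderm, stood at 11.91 ± 0.15 in endoderm and 4.84 ± 1.0 in mesenchyme (n = 3 each). Aldh1a1, which encodes a retinoic acid producing enzyme, stood at 4.23 ± 0.26 in endoderm and 11.77 ± 0.055 in mesenchyme. The signalling genes Ihh (log2 difference 4.32) and Shh (3.79) were higher in endoderm, while Gli1, a transcriptional target of Hedgehog signalling, was higher in mesenchyme (log2 difference -3.67).

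The 8 largest rises in endoderm were Lgals2 (7.26 ± 0.33), Foxa1 (7.07), Tspan8 (6.68, or 3.92 with the median of its probe sets), Cldn7 (6.22), Lad1 (6.14), Cldn4 (5.98), Rbp4 (5.97) and Rhpn2 (5.97). They include tight junction genes (Cldn7 and Cldn4), a galectin gene (Lgals2) and the gene of the retinol carrier of plasma (Rbp4). The 8 largest falls were Aldh1a1 (-7.53 ± 0.13), Col5a2 (-6.97), Cdh11 (-6.90), Actg2 (-6.88), Myh11 (-6.70, or -3.61 with the median of its probe sets), Aplnr (-6.67), Mest (-6.59) and Tcf21 (-6.50). Tspan8, Rbp4 and Rhpn2 lay under the 30th percentile in mesenchyme, and Aldh1a1, Cdh11, Myh11 and Aplnr in endoderm. Their limma adjusted p ranged from 9.5e-09 to 2.6e-06.

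Epithelial lists were higher in endoderm. All 26 junction and keratin genes tested were higher (26 adjusted over the list alone), by a median of 4.00, among them the adhesion genes Cdh1 (10.74 ± 0.12 against 5.19 ± 0.21) and Epcam (11.96 ± 0.14 against 6.41 ± 0.50). Of 22 intestinal transcription factor genes, 18 were higher (19 adjusted over the list alone), including Klf5 (5.84), Cdx2 (5.04 ± 0.21) and Hnf4a (4.73 ± 0.22). The Hnf4a difference was 2.82 with the median of its probe sets and 0.98 without cross-hybridizing probe set types. The camera adjusted p was 6.9e-16 for junction genes and 1.4e-08 for transcription factors, and with an estimated correlation the adjusted p was 0.06 and 0.097. Of 7 liver and pancreas genes, 3 were higher and 1 lower (4 and 1 adjusted over the list alone; camera adjusted p = 0.19), and the higher ones included Afp (5.84) and Ttr (4.22), which the yolk sac and early liver also express.

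Connective tissue, muscle, vessel and nerve lists were higher in mesenchyme. Of 21 stroma genes, 20 were lower in endoderm (20 adjusted over the list alone), with Col1a1 (-6.48) and Lum (-6.34) the furthest apart and Vim, the intermediate filament gene of mesenchymal cells, at -1.61. All 13 smooth muscle genes and all 14 endothelial genes were lower in endoderm (13 and 14 adjusted over the list alone), including Actg2, Myh11, the vascular receptor gene Kdr (-3.79) and Emcn (-3.50). Of 18 enteric neural crest and neuron genes, 17 were lower and 1 higher (17 and 1 adjusted over the list alone), led by Fabp7 (-5.00) and Tubb3 (-4.60), with the receptor gene Erbb3 as the higher one (1.68). Of 31 collagen and basement membrane genes, 25 were lower and 3 higher (25 and 3 adjusted over the list alone), and the higher ones were the laminin genes Lama1 (2.66), Lamb3 (2.06) and Lama5 (0.93). The camera adjusted p was 3.1e-13 for stroma, 2.2e-09 for smooth muscle, 3.7e-09 for endothelium, 2.5e-09 for neural genes and 3.7e-09 for collagens. With an estimated correlation the adjusted p was 0.097, 0.06, 0.047, 0.047 and 0.12 in that order. Lama1, Lamb3, Lama5 and Erbb3 were named after their values were seen.

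Blood cell genes also lay on the mesenchyme side. Of 13 myeloid genes, 10 were lower in endoderm (11 adjusted over the list alone), including the macrophage receptor gene Csf1r (-2.86, or -1.15 with the median of its probe sets) and C1qa (-1.47). Of 8 erythroid genes, 6 were lower (7 adjusted over the list alone), led by the embryonic globin genes Hba-x (-6.28) and Hbb-y (-5.28). Their camera adjusted p was 0.00046 and 0.00041, and with an estimated correlation the adjusted p was 0.16 and 0.13.

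Hedgehog ligand genes were higher in endoderm and Hedgehog target genes higher in mesenchyme. Of 3 Hedgehog ligand genes, too few for a set test, Ihh (8.81 ± 0.18 against 4.49 ± 0.42) and Shh (8.21 ± 1.1 against 4.42 ± 0.061) were higher in endoderm (2 adjusted over the list alone). Of 17 Hedgehog receptor and target genes, 14 were lower in endoderm (15 adjusted over the list alone), among them the receptor gene Ptch1 (-2.20 ± 0.098), Gli1 (-3.67), Foxf1 (-3.68), Tcf21 and Bmp4 (-4.61). Of 22 BMP pathway genes, 14 were lower and 1 higher (14 and 1 adjusted over the list alone), with Id4 lowest at -5.21 and Bmp2, named after its value was seen, higher by 1.72. Of 24 Wnt ligand and modulator genes, 13 were lower and 4 higher (13 and 5 adjusted over the list alone), including the antagonist gene Sfrp1 (-4.81) and the ligand gene Wnt5a (-4.26). Of 20 Notch pathway genes, 12 were lower (12 adjusted over the list alone), led by Hey1 (-2.16) and Notch4 (-2.05, or -1.20 with the median of its probe sets). As sets these had a camera adjusted p of 9.6e-09 for Hedgehog targets, 0.00015 for BMP, 0.008 for Wnt and 0.0027 for Notch genes, and with an estimated correlation the adjusted p was 0.06, 0.13, 0.12 and 0.29. Of 11 FGF pathway genes, 5 were higher and 4 lower (5 and 4 adjusted over the list alone; camera adjusted p = 0.84, its direction upward against a median of -0.09), from the receptor gene Fgfr4 (4.16, or 1.52 with the median of its probe sets) to Fgf13 (-3.39). Of 18 Hox genes, which pattern the body axis, 16 were lower in endoderm (16 adjusted over the list alone), including Hoxa5 (-5.27) and Hoxc8 (-4.77), with a camera adjusted p = 3.7e-09 and an adjusted p = 0.06 with an estimated correlation.

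**Figure D2:**
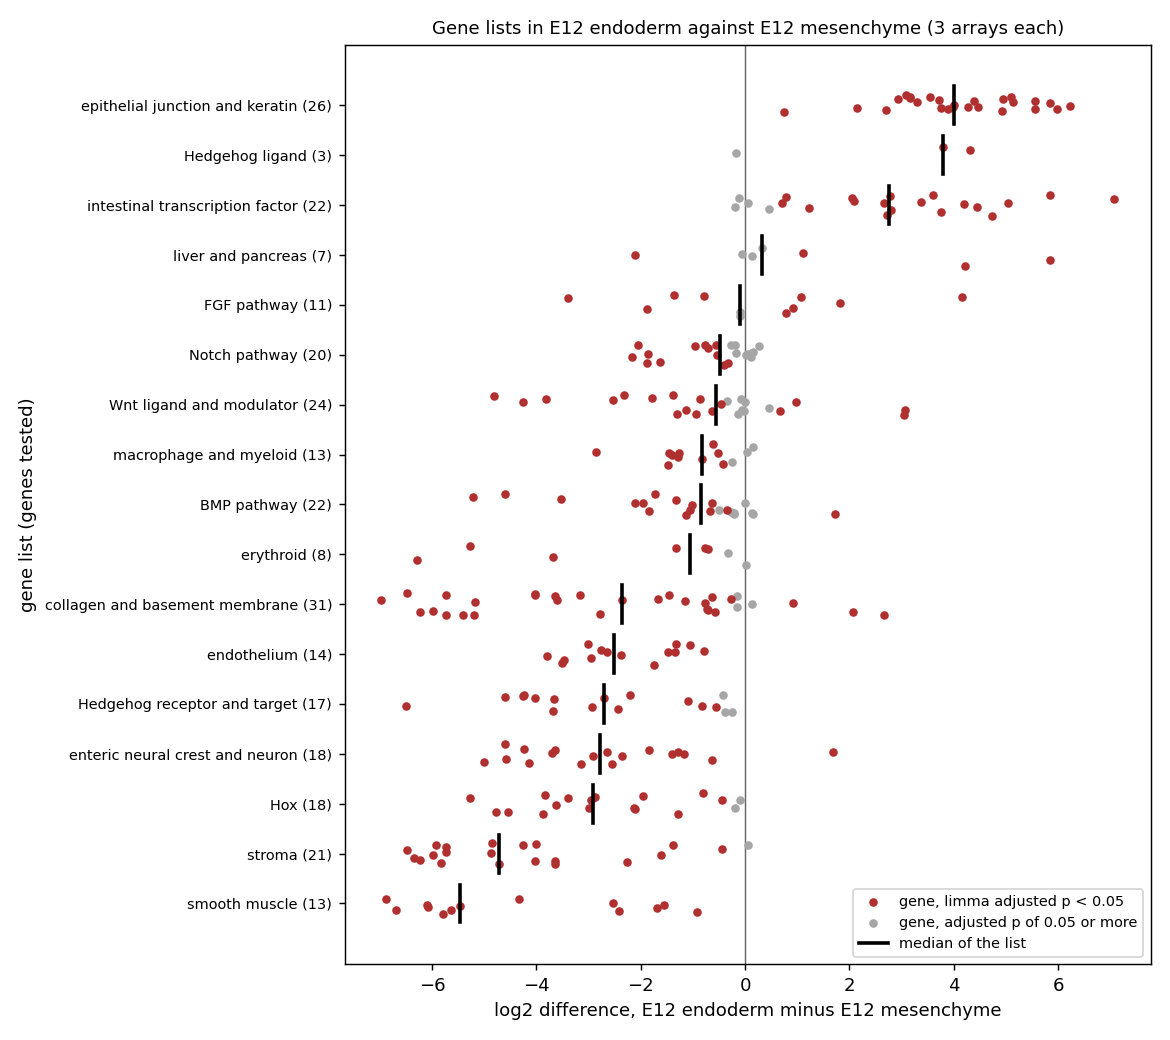
Log2 difference (E12 endoderm minus E12 mesenchyme, horizontal axis) of every tested gene in each list fixed for this comparison (vertical axis), with a black bar at the median of each list; red points passed the limma test and grey points did not. Medians run from -5.47 for smooth muscle genes to 4.00 for junction and keratin genes.

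Over all 9442 genes tested, 5010 differed between the layers in limma, 2615 higher and 2395 lower in endoderm, and 5514 had an unadjusted p under 0.05. By at least 2-fold, 831 were higher and 1017 lower. The arrays of the layers did not overlap for 62.0% of the genes, where chance gives 10%. Of the list calls above, those for endothelial and for neural crest and neuron genes held with an estimated correlation. In the pair from 35 fetuses, which lies in the other table, 94.25% of the 5010 called genes had the same direction. Of the 1848 genes that differed at least 2-fold, 99.8% had the same direction, and all 49 named genes did. The gap between the beta-actin probe sets was 1.48 in E12 endoderm replicate 2. The group means were 0.867 ± 0.539 in endoderm and 0.433 ± 0.0451 in mesenchyme (exact permutation test, two-sided p = 0.2). The Gapdh gap also set endoderm replicate 2 apart, at 0.97 against 0.16 and 0.18 in endoderm replicates 3 and 4.

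Crypts were compared with E12 endoderm, both of which hold dividing epithelial cells, in the table that holds both. Lyz1, Itln1 and Reg3g were among the largest gains in crypts, and Mdk and Igf2 among the largest losses. Lyz1 stood at 14.16 ± 0.063 in crypts (n = 3), the highest value of every crypt array, and at 5.21 in the E12 endoderm array, under its 30th percentile of 5.71, so the size of its difference is not measured at either end. Its probe set that is not prone to cross-hybridization stood at 9.10 in crypts and 7.10 in E12 endoderm. The growth factor gene Mdk stood at 7.24 ± 0.24 in crypts and 13.20 in E12 endoderm, a 62.3-fold difference. E12 endoderm has 1 array in this table, so its spread is not measured, and all p-values of crypts or villi against it assume that it varies like the other groups.

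The 8 largest rises in crypts were Lyz1 (2.01 without cross-hybridizing probe set types), the lectin gene Itln1 (8.40), Spink4 (8.23), the chemokine gene Ccl6 (7.31), the bactericidal lectin gene Reg3g (7.11), the antibody transporter gene Pigr (6.79), Clps (6.74) and the peptidoglycan recognition gene Pglyrp1 (6.48). The 8 largest falls were Mdk (-5.96 ± 0.23), Grb10 (-5.32, or -1.10 with the median of its probe sets), Peg3 (-5.11), the glucose carrier gene Slc2a3 (-4.86), the insulin-like growth factor gene Igf2 (-4.71), Jun (-4.55), the RNA-binding protein gene Igf2bp3 (-4.53) and Slc25a4 (-4.51). Lyz1, Itln1, Spink4, Ccl6, Reg3g and Pglyrp1 lay under the 30th percentile in E12 endoderm and Slc2a3 in crypts, so the order of the rises is not exact. Their limma adjusted p ranged from 1.4e-05 to 0.0022.

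Of 28 cell cycle genes, 26 were lower in crypts than in E12 endoderm (27 adjusted over the list alone), including Rrm2 (-3.08) and the replication helicase gene Mcm6 (-2.87). The set gave a camera adjusted p = 3.6e-13 and an adjusted p = 0.26 with an estimated correlation, while Mki67 itself differed by -0.29 ± 0.49 (limma adjusted p = 0.68), or by 0.04 after quantile normalization. Of 17 brush border genes, 5 were higher in crypts (7 adjusted over the list alone), led by the protease gene Mep1b (3.64) and Cdhr5 (2.87), with a camera adjusted p = 0.0016 and an adjusted p = 0.53 with an estimated correlation. Lct differed by 0.53 ± 0.66 (adjusted p = 0.58), or by 0.05 after quantile normalization. Of 21 fat absorption genes, 5 were higher and 2 lower (6 and 2 adjusted over the list alone; camera adjusted p = 0.12, or 0.025 without crypt replicate 12, and 0.025 to 0.83 over the alternatives), with the bile acid binding gene Fabp6 at 6.25 and Apoc2 at 4.11. Fabp6 had an adjusted p of 0.056 without crypt replicate 21 (0.0071 to 0.056 over the alternatives), and its crypt arrays ran from 8.82 to 12.4. Of 27 intestinal transcription factor genes, 6 were higher and 4 lower (7 and 4 adjusted over the list alone; camera adjusted p = 0.23), from the vitamin D receptor gene Vdr (4.15) to the repressor gene Prdm1 (-4.28). Hnf4a differed by 0.62 ± 0.24 (adjusted p = 0.096, or 0.013 after quantile normalization, and 0.013 to 0.23 over the alternatives), Cdx2 by -0.90 ± 0.46 (0.19, or 0.04 without villus replicate 41, which enters the estimate of the spread, and 0.04 to 0.46 over the alternatives) and Lgr5 by 0.27 ± 0.44 (0.67), or by -0.02 without crypt replicate 12, 0.59 without crypt replicate 41 and 0.60 after quantile normalization. After quantile normalization Hnf4a differed by 0.99 and Cdx2 by -0.59. Of 17 stroma genes, Vim (-3.74), Fn1 (-3.30, or -2.11 with the median of its probe sets) and Sparc (-1.11), the last named after its value was seen, were lower in crypts (2 adjusted over the list alone; camera adjusted p = 0.59). Of 7 erythroid genes, Hbb-y was lower (-1.40) and Epb42 higher (0.78; 1 and 1 adjusted over the list alone; camera adjusted p = 0.77), and Epb42 had an adjusted p of 0.071 without crypt replicate 21 and 0.074 after quantile normalization (0.011 to 0.074 over the alternatives).

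Villi were set against the same E12 endoderm array to follow the absorptive compartment. The 8 largest rises in villi were Reg3g (7.64 ± 0.63), the galectin gene Lgals3 (7.61), the goblet cell gene Clca1 (7.55, or 4.93 with the median of its probe sets), the lectin gene Clec2h (7.52), Fabp6 (7.33), Apoc3 (7.17), Mep1b (7.05) and Cd74 (6.95), the invariant chain gene of antigen presentation. The 8 largest falls were Bex1 (-7.29 ± 0.51), Mdk (-6.50), Grb10 (-5.40, or -1.15 with the median of its probe sets), Cks1b (-5.19), the chromatin protein gene Hmga2 (-5.15), Cnn3 (-5.14), Psat1 (-5.07) and Peg3 (-5.07). Reg3g, Lgals3, Clca1, Clec2h, Fabp6 and Apoc3 lay under the 30th percentile in E12 endoderm, and Bex1 and Psat1 in villi. Their limma adjusted p ranged from 1.4e-05 to 0.0044.

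In limma, 2348 of 10082 genes differed between crypts and E12 endoderm, 827 higher and 1521 lower in crypts, and 3946 differed between villi and E12 endoderm, 1715 higher and 2231 lower in villi. Both counts rest on the lone E12 endoderm array, and the first was 1357 without crypt replicate 21. The Dap poly-A control averaged 8.18 in the E12 arrays of this table and 3.82 in the adult arrays, so the preparation batch and the stage cannot be told apart in these counts. The gap between 3′ and 5′ probe sets also differed, at 0.101 in the E12 arrays and 0.717 in the adult arrays for beta-actin and 0.199 and 0.955 for Gapdh. The 18S control did not part them, at 7.35 and 7.60 in the E12 arrays and 7.36 to 13.4 in the adult arrays. Its highest adult values were in crypt replicate 41 (13.09) and villus replicate 41 (13.39).

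**Figure D3:**
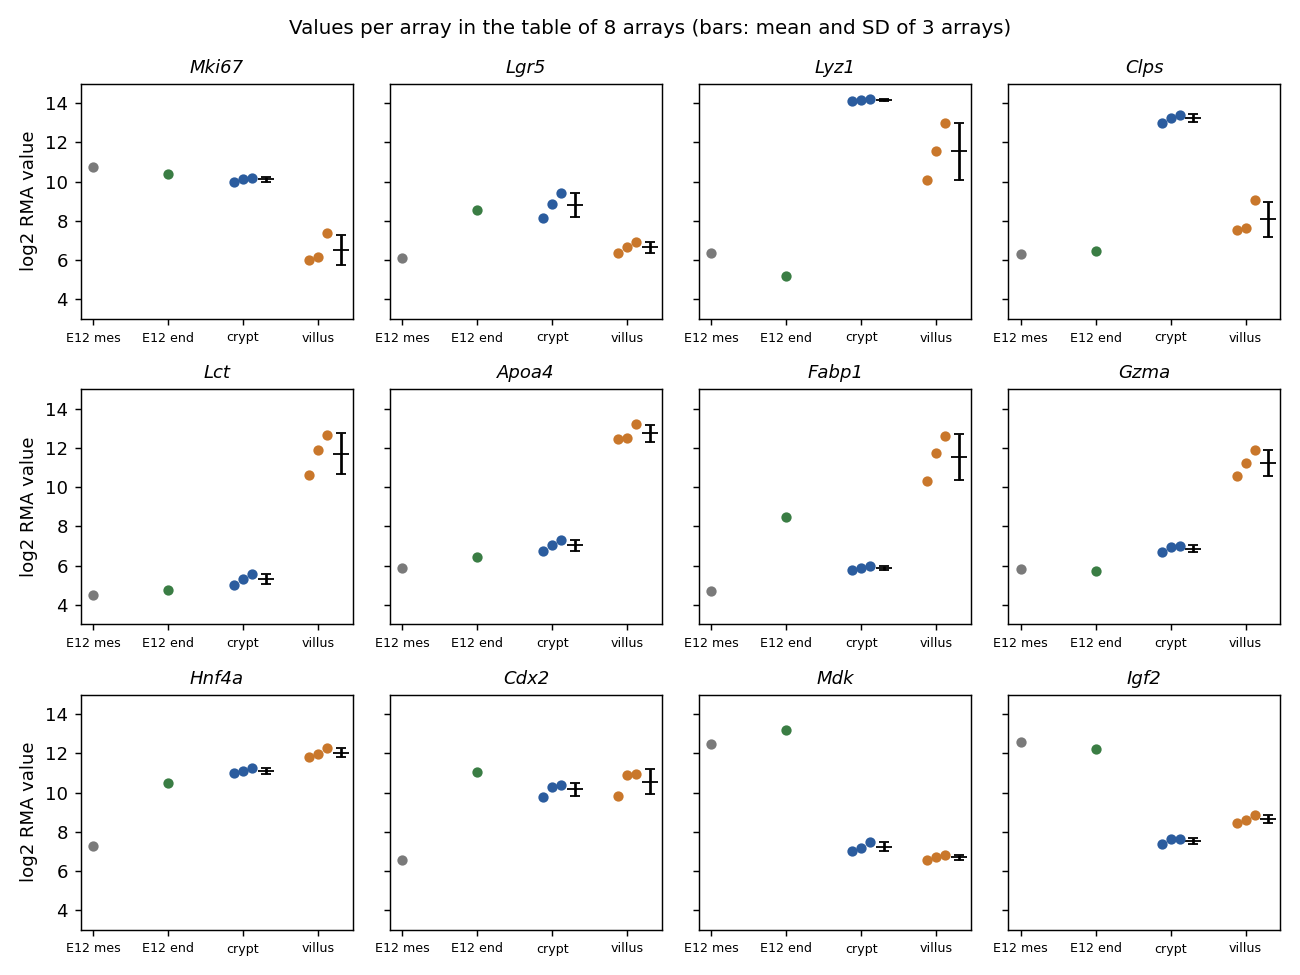
Log2 RMA value (vertical axis) of 12 genes in each array of the first table, by group (horizontal axis); points are arrays, and the bars give the mean and SD where a group has 3 arrays. Lyz1 and Clps peak in crypts, Lct, Apoa4, Fabp1 and Gzma in villi, and Mdk and Igf2 in the E12 arrays.

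Genes that marked the E12 layers were followed along the adult axis. Of 312 tested genes that were at least 4-fold higher in E12 endoderm, 123 were higher and 44 lower in villi than in crypts, with a median log2 difference of 0.47 (camera adjusted p = 5.8e-05, adjusted p = 0.17 with an estimated correlation). Of 300 tested genes at least 4-fold higher in E12 mesenchyme, 41 were higher and 26 lower in villi, with a median of 0.05 and a camera adjusted p = 0.25, which became 0.017 after quantile normalization. These lists came from E12 arrays that take no part in the adult comparison.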

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

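Tests in this part that weigh an explanation were chosen after the results were seen, apart from the splits of the samples, which were set before the data were examined. No group within a table had 4 arrays, so no array was tested as an outlier of its group.

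Control probe sets, which no comparison used, differed between arrays. The Dap poly-A control, an RNA that is added to a sample during preparation, averaged 8.18 in the E12 pair of the first table and 3.82 in the 6 adult arrays. The beta-actin 3′ minus 5′ gap was higher in crypts than in villi by 0.826 (exact permutation test, two-sided p = 0.1, the smallest possible here), while the same gap for Gapdh differed by -0.0454. E12 endoderm replicate 2 had a beta-actin gap of 1.48 and a Gapdh gap of 0.97. The E12 pair from 35 fetuses was outside the test of 3 against 3 arrays and entered the layers only in an alternative. Its differences had a slope of 0.727 on those of the 6 other E12 arrays across genes, which are not independent replicates. The pair lies on another array platform, and its array values had a mean SD of 1.93, against 2.31 in the 6 others. Pool, platform and scale cannot be told apart in this slope.

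Immediate-early genes, which respond within minutes to stimulation, were higher in villi: 10 of 17 tested rose, including Fos (4.21), Jun (3.81), Dusp1 (2.92) and Junb (2.75). This list was chosen after the data were seen, so its set test is not independent support. The set had a camera adjusted p of 1.8e-05, and an adjusted p of 0.54 with an estimated correlation. Against the lone E12 endoderm array, the list median was -1.0 in crypts and 0.31 in villi. That array came from collagenase-digested tissue of another stage, and the Dap control parted the E12 and adult arrays. The array therefore cannot serve as a baseline, and a low level in crypts stays as open as a high level in villi. The lowest villus array lay 1.2 above the highest crypt array in the mean over the list, against a largest SD between arrays of a group of 0.43, which argues against 1 villus array carrying the difference. Of 9 heat-shock genes, 0 were called higher and 3 were called lower in villi, with a list median of -0.7. By size, 2 lay above a log2 difference of 0.5 and 6 below -0.5. They ran from Dnajb1 at 1.31 (limma adjusted p = 0.065) to Hspe1 at -2.59. Members lay on both sides, so a general stress response stays open, although the called ones were all lower in villi. A difference in handling between the villus and crypt steps cannot be told apart from the groups, since each kind of preparation holds 1 group and the list's median difference was 1.2. A difference between the compartments in the animal also stays open and was not tested.

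Colipase (Clps) and the lipase-related gene Pnliprp2 (-4.18) were among the genes highest in crypts, where they stood at 13.22 and 12.38. RNA from the pancreas in the crypt preparations is argued against by 11 other pancreatic acinar genes, whose median crypt minus villus difference was -0.036. The abundant acinar genes Cela3b and Ctrb1 stood at 7.90 and 7.72 in crypts and at 7.94 and 7.82 in villi, near their levels in the E12 endoderm array (7.63 and 7.55), and Prss2 stood at 7.78 in crypts and 7.77 there. Of the 11, Reg1 is also expressed in intestine. Only Pnliprp1 (-1.32) and Rnase1 (-1.62) of the 11 were called, lower in villi by far less than Clps. Expression in crypt cells remains a hypothesis that these data leave open.

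T cell genes were higher in villi. A lower share of epithelium in the villus preparations would raise the other cell types whose RNA is present in them. The highest median among the myeloid, B cell, stroma and endothelium lists was only 0.13, against 1.58 for T cell genes. The B cell list holds Xbp1, which secretory epithelium also uses, and the cells behind Lyz2 in the myeloid list were not tested. The stroma and endothelium lists alone had medians of 0.06 and -0.05. All 5 tested CD3, CD8 and zeta chain genes rose, from Cd247 (0.39) to Cd3g (3.44), which is consistent with more T cells in the villus preparations. Cd3g stood at 7.69 to 8.91 in villi and at 4.75 to 4.87 in crypts. Whether this reflects the tissue or the isolation was not tested.

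With 6 arrays there are 10 splits into 3 and 3, too few for a share under 0.05. The real split of villi and crypts gave 3183 genes (1731 by at least 2-fold), and the highest of the other splits gave 0 (0) in limma, with 283 at an unadjusted p under 0.05. The real split was the only 1 of the 10 with as many genes. Every other split puts villus and crypt arrays in the same group, so a tissue difference adds to its spread. A low count there is built in and is no evidence for the real grouping. The real split of the E12 layers gave 5010 (1848), also the only 1 of 10, and the highest other gave 0 (0), with 136 at an unadjusted p under 0.05. Of the 4 E12 splits that part all 3 same-numbered pairs, those other than the real one also gave 0. All E12 splits other than the real one mix the layers, so the same limit applies to them.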

How the results depend on the processing

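No called named gene and no gene list call changed direction under an alternative that was run. Of named genes without a call, Chga and Cdx2 in villus against crypt and Mki67 in crypt against E12 endoderm changed sign after quantile normalization (-0.10, -0.09 and 0.04), and Lgr5 in crypt against E12 endoderm without crypt replicate 12 (-0.02). Counts of changed genes moved by over 1.5 times without crypt replicate 21, for villus against crypt (1974) and crypt against E12 endoderm (1357), and with the replicate block for villus against crypt. For villus against crypt, leaving out replicates gave 1974 to 3142 genes (1454 to 1977 by at least 2-fold), and the replicate block gave 1260 (1260 by at least 2-fold). That block rests on the 2 numbers shared by a crypt and a villus array, whose deviations correlated at 0.16 and 0.069, so it leaves fewer residual degrees of freedom. Treating the number as a random effect gave 3373. For crypt against E12 endoderm, leaving out replicates gave 1357 to 2977 genes, and for villus against E12 endoderm 3314 to 3949. For the E12 layers the replicate block gave 5089 genes (1849 by at least 2-fold) and changed no call of a named gene or list, and leaving out replicates gave 4260 to 5242. Genes of E12 endoderm in villus against crypt had an adjusted p of 0.17 with an estimated correlation, and those of E12 mesenchyme 0.017 after quantile normalization; the cause was not tested. Over the other settings of the 2 lists the adjusted p ran from 9.6e-05 to 0.0054 and from 0.11 to 0.73. With the median over probe sets, 20, 36, 40 and 33 of the called genes changed sign in the order of the comparisons in the report. Among named genes, all 733 results for the E12 layers and all 207 for villus against E12 endoderm kept their side of the threshold. For villus against crypt 973 kept it, 41 lost the call and 6 gained it, and for crypt against E12 endoderm 414 kept it, 3 lost it and 2 gained it. Gcg (0.053), Sc5d (0.063), Arg2 (0.085), Blnk (0.063), Xbp1 (0.053) and Ptprc (0.054) lost it only with the replicate block. Leaving out an array reduces the samples behind a test. Genes near the bottom of the signal range have compressed differences, and no detection calls were used.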

Other observations

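The gene groups in this part were chosen after seeing the data. Interferon response genes were higher in villi than in crypts: 7 of 11 rose, by a list median of 2.0, led by Oasl2 (3.88), Ubd (3.76), Ifit1 (3.69) and Irf7 (3.01). The set had a camera adjusted p of 0.00033, and an adjusted p of 0.54 with an estimated correlation. Villus replicate 12 had the lowest Ifit1 (7.52, against 10.1 and 10.4) and the lowest Ubd (6.65, against 10.1 and 10.8) of the villus arrays. That array also had the highest villus values of Mki67, Lyz1 and Clps, which are higher in crypts. Lct and Fabp1, which are higher in villi, were lowest in villus replicate 41 instead. Whether the low values of villus replicate 12 are particular to interferon genes was not tested. Genes of the response to amino acid shortage were higher in crypts: 9 of 18 were lower in villi and 1 higher, led by Nupr1 (-3.93), the serine synthesis gene Psat1 (-3.55), the asparagine synthetase gene Asns (-2.51) and Gpt2 (-2.18). Ddit3 was the higher one (0.81). That set had a camera adjusted p of 0.00033, and an adjusted p of 0.54 with an estimated correlation.

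Imprinted genes of growth control were lower in crypts than in E12 endoderm, which has 1 array and no measured spread: 9 of 11 fell, by a list median of -2.4, including Grb10 (-5.32, or -1.10 with the median of its probe sets), Peg3 (-5.11), Igf2 (-4.71) and Cdkn1c (-3.58). The set had a camera adjusted p of 3.8e-08, and an adjusted p of 0.24 with an estimated correlation. The fetal genes Mdk (-5.96), Igf2bp3 (-4.53) and Hmga2 (-4.22) were lower in crypts too. Between the E12 layers, 10 of 13 imprinted genes were lower in endoderm and 1 was higher. The set had a camera adjusted p of 0.00026 and an adjusted p of 0.27 with an estimated correlation.

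Some clock genes, but not all, set the arrays numbered 12 of both adult tissues apart. Arntl was highest in crypt replicate 12 (6.23) and villus replicate 12 (7.39), against 5.44 to 5.61 and 5.68 to 5.96 in the other arrays of each group. Dbp, an output gene of the clock, was lowest in the same arrays (6.75 and 6.01, against 7.55 to 8.26 and 8.11 to 8.62), and so was Nr1d2 (7.44 and 6.87, against 8.16 to 8.56 and 8.86 to 8.95). Nr1d1 was low in villus replicate 12 (7.84, against 9.37 to 9.83) but crypt replicate 12 (7.56) lay between the other crypt arrays (7.53 and 7.57). Xist, expressed from the inactive X chromosome, stood at 12.4 in crypt replicate 21 and 9.20 in villus replicate V275, and at 7.61 to 8.26 in the adult arrays numbered 12 and 41. The Y-linked Eif2s3y stood at 3.83 and 3.21 in the first 2 of these arrays and at 5.76 to 6.73 in the others. These values are reported without a test.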
